A study of Mus musculus with 6 samples.

How the data were processed

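The samples were 6 RNA-seq libraries of mouse bone marrow neutrophils, 3 treated with 10 µM PGE2 and 3 with vehicle for 24 h. Per the labels' protocols, the cells were purified on a Percoll density gradient, RNA was taken with TRIzol, and libraries were made with a TruSeq mRNA kit, which the labels name both as standard and as stranded. The series design states biological replicates. Groups and replicate numbers came from the sample titles.

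Per the submitters' processing notes, Bowtie2, STAR, StringTie 2.1.3b, RSEM and DESeq2 were used and the genome build was mm10; which tool made which values, and whether counting used the strand, is not given in the sources used here. The deposited table of the whole series holds estimated counts per gene as whole numbers. Its name calls them normalized, but their totals differ between libraries, and they were used as unnormalised estimated counts. For 417 of 478 single-exon genes with at least 200 counts in the first library, the deposited coverage times the gene's span divided by the count came to 101 bases after rounding, as a count made from read coverage would give, so the values count reads and not fragments. The authors' per-library tables give TPM and coverage per gene, per the file headers. Coordinates in those files were the same as in RefSeq GRCm38.p6 for 96.4% of the matched genes. The series table also held 18 columns of 6 libraries outside the samples given here, which were not used.

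Estimated counts were rounded to whole numbers. Genes with a count of at least 10 in at least 3 libraries were tested, 15947 of 45777. The test was edgeR 4.0.16's quasi-likelihood test with TMM scaling, two-sided, with Benjamini-Hochberg adjustment at 0.05 and no minimum fold, in R 4.3.3. Errors of log2 fold changes are standard errors from that test, and CPM values are means with SDs over 3 libraries. The biological coefficient of variation was 22.4%. In gene lists, camera of limma 3.58.1 was run on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, for 37 lists with at least 5 measured members, and fry was run beside it. The lists, the rule for named genes and the first set of alternatives given below were fixed before the data were examined. That rule took the 12 largest rises and 12 largest falls among genes that passed, with groups that did not overlap, a mean count of at least 100 and a symbol that is not a provisional name. It added the 4 PGE2 receptor genes, the 4 members of each list with the smallest adjusted p with up to 2 that passed in the other direction, and the 2 most abundant members of each list of other cells. Ribosomal protein, mitochondrial ribosomal protein, proteasome, translation initiation factor and clock gene families were chosen after their values were seen, and were taken by gene symbol, without kinases, binding proteins, assembly chaperones and pseudogenes that share a prefix.

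The test was run on simulated data first. Counts for this comparison were drawn from the real means, library sizes and dispersions, with 200 genes changed, and 15484 genes passed the filter. The test found 13.8% of genes changed 1.5-fold, 56.9% of those changed 2-fold and 82.8% of those changed 4-fold, and 9.17% of its calls were false. With 200 genes changed and 3 libraries per group, most changes of 1.5-fold were thus missed. The real comparison called 3896 genes, where the adjustment is less strict, so these shares do not carry over to it directly. In a simulated length trend with a log2 slope of -0.2 per doubling of length, 940 of 15508 unchanged genes were called, and 1 after the trend was removed. That trend was stronger than in the real libraries, whose slopes ran from -0.053 to 0.073. It was made from the same lengths that were used to remove it. It thus checks the removal step and does not size the false calls in these data.

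Pairing was checked by correlating the deviations from the group means. Same-numbered libraries correlated at 0.26, 0.17 and 0.19, and each library correlated most with the one of its own number, so the numbers were taken to pair the libraries. With 3 libraries per group few matchings are possible, and the same-numbered one could come out highest without true pairs. The pairing comes from the numbers in the titles and these correlations, and the labels do not say what a number stands for. For that reason the main test left the pairing out, and a fit with the replicate number as a block was run as an alternative. Replicates of one group correlated at 0.961 to 0.981 (Pearson's r of log2 CPM) and differed by more than sampling noise, with a chi-square per gene of 32.5 to 118.

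The first set of alternatives was the replicate block, each library left out, DESeq2 1.42.0 size factors, DESeq2's Wald test, no filter and a filter of 50 counts, the authors' TPM as log2(TPM + 1) with limma for genes with a TPM of at least 1 in 3 libraries, a minimum log2 fold change of 1, and camera with an estimated correlation. Chosen after the data were seen were library totals without TMM, removal of hemoglobin genes, halved counts, and a trend with transcript length and GC content removed per library with mgcv 1.9.3, with and without the block. Length came from the deposited counts and coverage, or from the longest GENCODE transcript, and 91.2% of tested genes had both values. Reads shared between paralogs or overlapping genes were counted as the authors counted them. Values of some named genes are not reported here.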

Results

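RNA was sequenced from neutrophils of the bone marrow of wild-type C57BL/6 mice after 24 h in culture with 10 µM prostaglandin E2 (PGE2, a lipid mediator that acts through the receptors EP1 to EP4) or with its DMSO vehicle. Each group held 3 libraries, which the series design states to be biological replicates. The deposited read counts totalled 42091346 to 56238941 per library, and 18242 to 19511 genes had at least 1 count. The comparison asks how PGE2 changed gene expression in these cells. On a principal component plot of log2 CPM (CPM is the read count scaled to the size of the library), the first component carried 46.2% of the variance and placed the 3 PGE2 libraries at -26.6, -69.8 and -44.6 and the 3 vehicle libraries at 60.5, 40.3 and 40.2. Hemoglobin genes, which red cells and their precursors express, took 1.57, 4.87 and 2.51% of the counts in PGE2 replicates 1, 2 and 3 and 0.41, 1.86 and 1.11% in vehicle replicates 1, 2 and 3.

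With PGE2, 16 of 25 measured targets of cAMP signalling, 7 of 13 chemokine genes and the cytokine genes Il1b and Osm were higher. Lower were 19 of 30 interferon-stimulated genes, 13 of 19 genes of specific and gelatinase granules, 6 of 10 NADPH oxidase genes and 7 of 16 adhesion molecule genes. With an estimated correlation between members, limma's camera test called 0 lists. Thbs1, which encodes the matrix protein thrombospondin 1, went from 1276 ± 226 to 14210 ± 1927 CPM (mean ± SD, n = 3 per group), a log2 fold change of 3.48 ± 0.18 (SE). Oasl2, an interferon-stimulated gene of the oligoadenylate synthetase family, went from 139 ± 15.2 to 37.1 ± 2.53 CPM, a log2 fold change of -1.91 ± 0.11. Of 15947 genes tested with edgeR's quasi-likelihood test, 1618 were higher and 2278 lower with PGE2, which together were 24.4% of the genes. Among them 404 were higher and 602 lower by at least 2-fold. Protein-coding genes made up 1363 of the higher and 2049 of the lower genes. All 3 PGE2 libraries lay above all 3 vehicle libraries in 1613 of the higher genes, and below them in 2276 of the lower genes. Over the tested genes, 42.3% had groups that did not overlap in this way, where exchangeable libraries would give 10% on average. Genes are not independent of each other, so that share is not a test. With the replicate number as a block, 2648 genes were higher and 3009 lower. Without PGE2 replicate 2 the higher genes numbered 1063, and without vehicle replicate 2 they numbered 1005. Higher genes made up 41.5% of the calls with TMM scaling, 55.5% when libraries were scaled by their totals alone and 30% on the deposited TPM values.

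The 12 largest rises under the rule for named genes came from genes that averaged at most 3.64 CPM in vehicle. For each gene named here that passed without the block, all 3 PGE2 libraries lay on one side of all 3 vehicle libraries. Vgf, which encodes a secreted neuropeptide precursor (chromosome 5, 137025301 to 137033351, mm10), had 0 counts in the 3 vehicle libraries and 2.1, 10.1 and 1.38 CPM in the PGE2 libraries, and was at least 201-fold higher against a floor of 3 counts over the vehicle group. Without PGE2 replicate 2 that limit was at least 78.3-fold. Peg10, an imprinted gene derived from a retrotransposon (chromosome 6, 4747306 to 4760517), rose from 0.300 ± 0.116 to 109 ± 49.2 CPM, with a log2 fold change of 8.53 ± 0.46. Pla1a, a phospholipase gene (chromosome 16, 38396117 to 38433191), rose from 0.715 ± 0.362 to 50.2 ± 13.4 CPM. Mpzl2, a cell adhesion gene (chromosome 9, 45042344 to 45054043), rose from 3.64 ± 1.69 to 172 ± 40.5 CPM. The homeobox gene Dlx1 rose by 5.5 ± 0.43, the mucin gene Muc3 by 5.43 ± 1.03 and Efr3b by 4.14 ± 0.41 on the log2 scale. Muc3 was at 4.60, 7.95 and 4.79 without PGE2 replicate 2, vehicle replicate 2 and vehicle replicate 3. Hilpda, a lipid droplet gene, and its neighbour on chromosome 6, Fam71f2, rose by 4.93 ± 0.52 and 6.07 ± 0.72, and Fam71f2 was at 7.45 without vehicle replicate 3. Mospd4, a transcribed pseudogene, rose by 4.58 ± 0.37. The protease gene Prss8 rose by 4.25 ± 0.42 and Fosl1, an AP-1 transcription factor, by 4.03 ± 0.51 (4.95 without vehicle replicate 1). Mospd4 overlaps Gm4107 on the same strand and can share reads with related genes, and Prss8 and Fosl1 overlap Kat8 and Ccdc85b on the other strand, so their values are uncertain. On log2(TPM + 1), where the added 1 shrinks changes of low values by construction, the rises ran from 1.21 (Efr3b) to 4.90 (Mpzl2), with Peg10 at 4.59, Dlx1 at 3.09 and Muc3 at 2.08, and Vgf was not tested. The edgeR adjusted p of these 12 genes lay between 9.32e-05 (Peg10) and 0.00661 (Muc3).

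The 12 largest falls under the same rule began with the interferon-induced paralogs Ifit3 and Ifit3b. Ifit3 (chromosome 19, 34583119 to 34588982) went from 34.9 ± 8.80 to 3.47 ± 1.23 CPM, a log2 fold change of -3.33 ± 0.29, and Ifit3b (chromosome 19, 34607530 to 34613403) from 23.7 ± 6.19 to 2.38 ± 0.721 CPM, a log2 fold change of -3.31 ± 0.27. How the counting divided reads between these close paralogs is not given in the sources used here. Itih5, an inter-alpha-trypsin inhibitor heavy chain gene (chromosome 2, 10153536 to 10256529), fell by 3.05 ± 0.15 on the log2 scale, from 41.97 ± 7.11 to 5.07 ± 0.314 CPM. Nat8l, which encodes the enzyme that makes N-acetylaspartate, went from 66.2 ± 2.83 to 11.2 ± 4.34 CPM. Log2 fold changes were -2.93 ± 0.44 for Tex15, -2.92 ± 0.28 for Igf2bp2, -2.90 ± 0.34 for Chil5, -2.84 ± 0.22 for the integrin gene Itga8, -2.75 ± 0.25 for Gpr27 and -2.50 ± 0.16 for Crtac1. On log2(TPM + 1) Tex15 was at -1.77, Igf2bp2 at -1.45, Itga8 at -1.21, Itih5 at -2.33 and Gpr27 at -2.04. Ifit3b overlaps Ifit1bl1, Chil5 overlaps LOC115489728 and Gpr27 overlaps Eif4e3, each on the other strand. The lactase gene Lct, at -3.02 ± 0.89, passed with an edgeR adjusted p of 0.0402, and that p was 0.102, 0.131, 0.0617 and 0.0779 without PGE2 replicate 3, vehicle replicate 1, vehicle replicate 2 and vehicle replicate 3. Without PGE2 replicate 1 its log2 fold change was -3.89. Its adjusted p was 0.11 with DESeq2, and over the alternatives it ranged from 0.00376 to 0.131. Ear6, an eosinophil-associated ribonuclease gene with close paralogs, was at -2.53 ± 0.66 with an edgeR adjusted p of 0.0258, and at 0.0777, 0.0904 and 0.0802 without PGE2 replicate 2, PGE2 replicate 3 and vehicle replicate 2 (0.0104 to 0.0904 over the alternatives). Ear6 was at -3.28 without PGE2 replicate 1 and -1.69 without vehicle replicate 2.

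**Figure D1:**
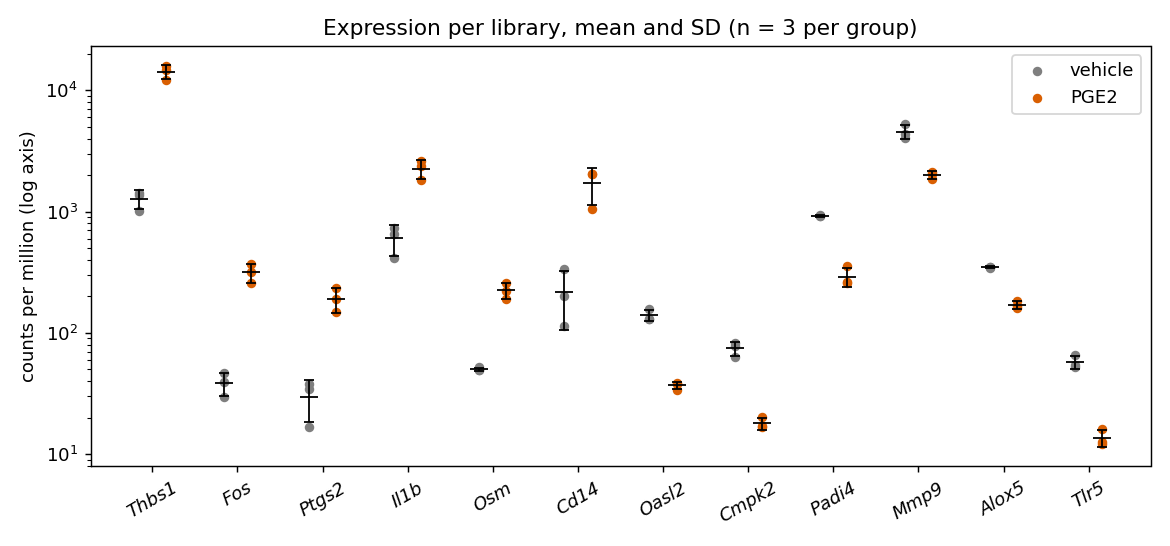
Expression of 12 genes in each library, in CPM on a log axis; points are libraries, bars are the mean and SD of 3 libraries per group. Thbs1 averaged 1276 in vehicle and 14210 in PGE2, and Oasl2 averaged 139 and 37.1.

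Genes of cAMP signalling rose together. Of 25 measured cAMP and CREB targets, 16 rose, 1 fell and 8 did not pass, and 17 rose and 1 fell when adjusted over the list alone. Their median log2 fold change was 1.24, and the limma camera test with a preset correlation called the list higher (adjusted p = 2.21e-07; adjusted p = 0.522 with an estimated correlation). Fos, an immediate early gene, rose from 38.5 ± 8.38 to 316 ± 57.2 CPM. The phosphodiesterase genes Pde7b and Pde3b, whose products break down cAMP, rose by 2.08 ± 0.13 and 1.76 ± 0.13 on the log2 scale. Sgk1, a kinase gene of the list, fell by 0.61 ± 0.08. Of 15 measured genes for prostanoid receptors and for the making or breakdown of PGE2, 3 rose and 5 fell, the same counts as when adjusted over the list alone, and camera did not call the list (adjusted p = 0.293). Ptgs2, which encodes the inducible cyclooxygenase, rose from 29.8 ± 11.5 to 191 ± 43.9 CPM. Tbxas1, which encodes thromboxane synthase and overlaps Hipk2, had a log2 fold change of -1.39 ± 0.14. The transporter gene Abcc4 was at -1.12 ± 0.18 and the phospholipase gene Pla2g4a at -0.72 ± 0.12. The EP2 receptor gene Ptger2 went from 20.9 ± 2.97 to 29.9 ± 4.86 CPM with an edgeR adjusted p of 0.0422. That p was 0.126, 0.0918, 0.109 and 0.111 without PGE2 replicate 2, PGE2 replicate 3, vehicle replicate 1 and vehicle replicate 2, 0.113 on TPM and 0.0546 with no filter (0.00408 to 0.126 over the alternatives). The EP4 receptor gene Ptger4 was at 16.9 ± 0.798 and 17.4 ± 1.74 CPM, and the EP3 receptor gene Ptger3 at 0.699 ± 0.22 and 0.405 ± 0.284 CPM in vehicle and PGE2. Neither of these receptor genes passed the edgeR test (adjusted p = 0.858 and 0.476).

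Inflammatory mediators moved in both directions. Of 14 measured proinflammatory cytokine genes, 6 rose and 3 fell, and 7 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.3, not called). Il1b rose from 602 ± 168 to 2263 ± 406 CPM and Osm, of the interleukin 6 family, from 50.4 ± 1.48 to 224 ± 33.4 CPM. Tnf went down from 63.3 ± 14.8 to 25.2 ± 1.77 CPM, and the TNF family ligand genes Tnfsf13b and Tnfsf14 had log2 fold changes of -1.75 ± 0.17 and -1.28 ± 0.16. Of 13 measured chemokine genes, 7 rose and 1 fell, the same counts as when adjusted over the list alone. Their median log2 fold change was 0.69, and camera called the list higher (adjusted p = 0.0156; adjusted p = 0.688 with an estimated correlation). With a length and GC trend removed the median was 0.35 (0.42 with GENCODE lengths), and with the block as well it was 0.3 and camera's adjusted p 0.0704 (0.00139 to 0.688 over the alternatives). The median was 1.13 with no filter. Ccl9 rose from 78.8 ± 4.28 to 339 ± 26.4 CPM, and the neutrophil-attracting Cxcl2 from 19.3 ± 8.35 to 169 ± 62.8 CPM. Ccl3, which overlaps Ccl4 on the other strand, rose by 1.00 ± 0.14 on the log2 scale, and the interferon-induced Cxcl10 fell by 1.52 ± 0.31. Of 22 measured NF-kB target genes, 8 rose and 4 fell, 11 rose and 4 fell when adjusted over the list alone, and 14 rose and 4 fell with the replicate block, while 5 rose without vehicle replicate 2. Camera gave this list an adjusted p of 0.0697, and 0.0254 with the block. Of 23 suppressive or alternative activation genes, 8 rose and 4 fell, 8 rose and 6 fell when adjusted over the list alone, and 8 rose and 7 fell with the block, while 2 fell without PGE2 replicate 2 and 2 without vehicle replicate 2 (camera adjusted p = 0.293). Pdcd1lg2, a ligand of the inhibitory receptor PD-1, rose from 1.93 ± 0.387 to 12.5 ± 1.00 CPM, and the decoy receptor gene Il1r2 from 143 ± 38.8 to 570 ± 91.1 CPM. Of 15 measured angiogenic and tissue remodelling genes, 4 rose and 3 fell, as when adjusted over the list alone, and 2 rose without vehicle replicate 2 (camera adjusted p = 0.675). Spp1, which encodes osteopontin, rose from 46.3 ± 3.15 to 549 ± 147 CPM, and Hgf had a log2 fold change of -1.58 ± 0.26.

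Interferon-stimulated genes fell as a group. Of 30 measured, 19 fell and 11 did not pass, and 20 fell and 1 rose when adjusted over the list alone. Their median log2 fold change was -0.72, and camera called the list lower (adjusted p = 7.38e-09; adjusted p = 0.397 with an estimated correlation). Beside Oasl2, Cmpk2 went from 74.6 ± 10.3 to 17.99 ± 2.01 CPM and Rtp4 from 50.04 ± 5.05 to 17.0 ± 1.66 CPM. Of 21 measured genes of Toll-like receptors and adaptors, 5 rose and 5 fell, 5 rose and 8 fell when adjusted over the list alone, and 6 rose and 9 fell with the block (camera adjusted p = 0.314). The Toll-like receptor genes that fell numbered 3, 2, 2 and 3 without PGE2 replicate 2, PGE2 replicate 3, vehicle replicate 2 and vehicle replicate 3. Cd14, a co-receptor for lipopolysaccharide, rose from 217 ± 110 to 1715 ± 571 CPM, while the flagellin receptor gene Tlr5 went from 57.3 ± 6.89 to 13.7 ± 2.26 CPM. Of 20 phagocytic and Fc receptor genes, 2 rose and 6 fell, 3 rose and 8 fell when adjusted over the list alone, and 5 rose and 8 fell with the block (camera adjusted p = 0.431). Clec4e rose by 0.97 ± 0.10, and Siglece, an inhibitory lectin receptor gene, fell by 1.39 ± 0.13 on the log2 scale. Of 15 chemotaxis receptor genes, 2 rose and 6 fell, as when adjusted over the list alone, and 1 rose without each of PGE2 replicate 2, vehicle replicate 1 and vehicle replicate 2 (camera adjusted p = 0.205). Of 18 antigen presentation genes, 4 rose and 3 fell, as when adjusted over the list alone, and 5 rose and 6 fell with the block, while 1 fell without each of PGE2 replicate 2, vehicle replicate 2 and vehicle replicate 3 (camera adjusted p = 0.794). The co-stimulatory ligand gene Cd80 rose from 22.1 ± 1.44 to 144 ± 24.1 CPM, and the peptide transporter gene Tap1 had a log2 fold change of -0.58 ± 0.13.

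Genes for the contents of specific and gelatinase granules fell. Of 19 measured, 13 fell and 6 did not pass, and 15 fell and 1 rose when adjusted over the list alone, while 8 fell without PGE2 replicate 3. Their median log2 fold change was -0.95, and camera called the list lower (adjusted p = 2.89e-05; adjusted p = 0.607 with an estimated correlation). Mmp9, which encodes gelatinase B, went from 4556 ± 616 to 2006 ± 136 CPM, Lyz2, a lysozyme gene, from 13430 ± 697 to 6451 ± 799 CPM, and Cd177 from 1275 ± 201 to 441 ± 164 CPM. Of 11 measured azurophil granule genes, 1 rose and 2 fell, as when adjusted over the list alone, and 2 rose and 5 fell with the block (camera adjusted p = 0.238). The granule proteoglycan gene Srgn rose by 1.80 ± 0.17, and the myeloperoxidase gene Mpo fell by 0.99 ± 0.12 on the log2 scale. Of 10 measured NADPH oxidase genes, 6 fell, and 7 fell when adjusted over the list alone. Camera called this list lower, with a median log2 fold change of -0.39 (adjusted p = 0.00722; adjusted p = 0.498 with an estimated correlation). The subunit gene Ncf1 went from 2256 ± 339 to 1312 ± 152 CPM and the regulator gene Rac2 from 1767 ± 201 to 1173 ± 39.5 CPM. Of 16 measured adhesion molecule genes, 7 fell, as when adjusted over the list alone, and camera called the list lower, with a median of -0.31 (adjusted p = 0.0102; adjusted p = 0.397 with an estimated correlation). The integrin genes Itgal and Itgb2, which encode the chains of LFA-1, had log2 fold changes of -0.87 ± 0.08 and -0.97 ± 0.10, and Ceacam1 was at -1.76 ± 0.22. Of 8 measured leukotriene and lipoxygenase genes, 2 fell, as when adjusted over the list alone, and 5 fell with the block. Camera called this list lower, with a median of -0.75 (adjusted p = 0.025; adjusted p = 0.498 with an estimated correlation), and its adjusted p was 0.0515 without PGE2 replicate 3, 0.0588 with no filter, 0.0643 with the stricter filter and 0.058 on TPM (0.0131 to 0.498 over the alternatives). Its median was -0.45 with no filter and -0.46 with the stricter one. Those that fell were Alox5, which encodes 5-lipoxygenase, from 348 ± 5.43 to 171 ± 12.8 CPM, and the leukotriene B4 receptor gene Ltb4r1, from 79.8 ± 5.07 to 37.7 ± 1.43 CPM. Of 13 measured genes of extracellular trap formation and lytic death, 2 rose and 3 fell, 3 rose and 3 fell when adjusted over the list alone, and 4 rose and 4 fell with the block (camera adjusted p = 0.687). In that list 1 gene rose without each of PGE2 replicates 2 and 3 and vehicle replicates 2 and 3. Padi4, which encodes a histone-citrullinating enzyme, went from 919 ± 12.4 to 292 ± 54.0 CPM, and the gasdermin gene Gsdme from 156 ± 2.46 to 62.0 ± 11.0 CPM.

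**Figure D2:**
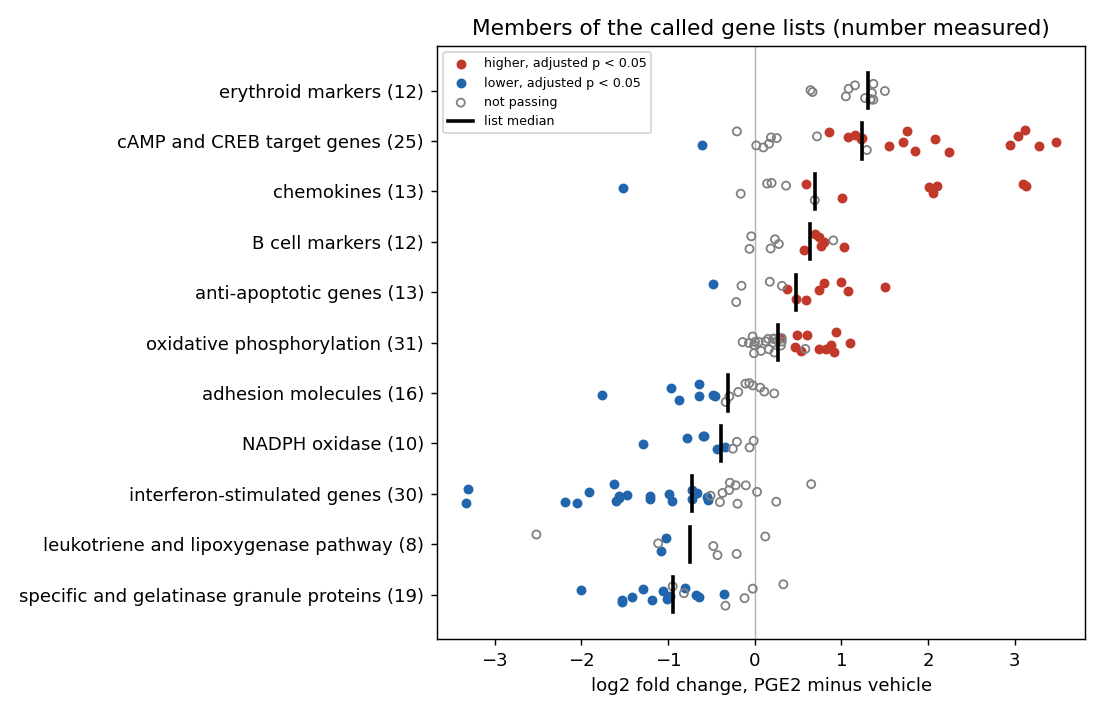
Log2 fold change (PGE2 minus vehicle) of each measured member of the 11 lists that camera called with a preset correlation; filled points passed the edgeR test, open points did not, and black bars are list medians. Medians ran from 1.31 for erythroid markers, of which 0 passed, to -0.95 for specific and gelatinase granule genes.

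Of 13 measured anti-apoptotic genes, 8 rose and 1 fell, as when adjusted over the list alone, and 5 rose without PGE2 replicate 2 and 5 without vehicle replicate 3. Camera called the list higher, with a median of 0.48 (adjusted p = 0.0131; adjusted p = 0.498 with an estimated correlation). Bcl2a1d and Bcl2a1b, close paralogs whose values are uncertain where they share reads, rose by 1.51 ± 0.17 and 1.08 ± 0.13 on the log2 scale, Pim2 rose by 0.80 ± 0.11, and Xiap fell by 0.48 ± 0.08. Of 18 measured pro-apoptotic genes, 2 rose and 6 fell, 3 rose and 6 fell when adjusted over the list alone, and 5 rose and 6 fell with the block, while 3 fell without PGE2 replicate 2 and 3 without vehicle replicate 3 (camera adjusted p = 0.448). Bbc3 was at -0.71 ± 0.14, and Bcl2l11, which encodes Bim, at 0.99 ± 0.21. Of 31 measured oxidative phosphorylation genes, 11 rose and 20 did not pass, and 12 rose when adjusted over the list alone. Camera called this list higher, with a median of 0.27 (adjusted p = 0.000198; adjusted p = 0.397 with an estimated correlation). The share of counts from the mitochondrial chromosome was 1.24 to 1.34% in the PGE2 and 0.9 to 0.999% in the vehicle libraries. Cox6c rose from 36.5 ± 2.44 to 67.3 ± 0.613 CPM and Cox7a2, which overlaps Tmem30a on the same strand and is uncertain for that, from 39.0 ± 2.71 to 73.6 ± 7.14 CPM. Fold changes also followed transcript length: the median log2 fold change was 0.263 in the 3012 genes with the shortest transcripts and -0.141 in the 3012 with the longest. With a length and GC trend removed, the oxidative phosphorylation median was 0.08 and camera did not call the list (adjusted p = 0.169, and 0.232 with the block as well). With GENCODE lengths the median was 0.14 and camera called the list (adjusted p = 0.0432, and 2.08e-05 to 0.397 over the alternatives). On TPM the list median was 0.14 as well, and camera called the list (adjusted p = 0.00222). The median of all tested genes was -0.064 on TPM, against 0.038 in the main test. Of 22 measured glycolysis genes, 3 rose and 7 fell, and 3 rose and 9 fell when adjusted over the list alone (camera adjusted p = 0.11). The lactate exporter gene Slc16a3, which overlaps Csnk1d, rose by 1.28 ± 0.15, and Pfkfb4 and the hexokinase gene Hk3 fell by 1.39 ± 0.11 and 0.77 ± 0.09 on the log2 scale. Of 21 genes of cholesterol synthesis and efflux, 2 rose, as when adjusted over the list alone, and 4 rose and 4 fell with the block, while 1 rose without each of PGE2 replicates 2 and 3 and vehicle replicate 2 (camera adjusted p = 0.794). The efflux transporter gene Abca1 rose from 11.0 ± 0.999 to 47.6 ± 15.2 CPM. Of 18 unfolded protein and stress response genes, 5 rose, and 5 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.11). The transcription factor gene Atf4 rose by 0.77 ± 0.08. Of 18 antioxidant genes, 5 rose, as when adjusted over the list alone, and 9 rose and 1 fell with the block (camera adjusted p = 0.11). The cystine transporter gene Slc7a11 rose from 434 ± 60.5 to 888 ± 110 CPM. Of 26 measured cell cycle genes, Ube2c, Pcna and Aurka rose in the test over all genes, and 9 rose and 1 fell with the block. When adjusted over the list alone, 0 cell cycle genes passed edgeR's test, where 9 had an unadjusted p under 0.05 and DESeq2 called 5 higher and 1 lower over all genes. Those that rose numbered 1, 0, 1 and 0 without PGE2 replicate 1, PGE2 replicate 3, vehicle replicate 1 and vehicle replicate 2. Camera gave the cell cycle list an adjusted p of 0.054, and 0.0108 with the block.

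Markers of other bone marrow cells, which a density gradient can leave in the preparation, moved apart. Of 12 measured B cell markers, 6 rose, as when adjusted over the list alone, and 9 rose with the block, 3 without vehicle replicate 1, 3 without vehicle replicate 2, 3 on TPM and 2 with the length trend removed. Camera called the B cell list higher, with a median log2 fold change of 0.63 (adjusted p = 0.0131; adjusted p = 0.715 with an estimated correlation), and without PGE2 replicate 3 its adjusted p was 0.0561 (0.00112 to 0.715 over the alternatives). The light chain gene Igkc rose from 139 ± 11.8 to 206 ± 17.3 CPM, with an edgeR adjusted p of 0.00479 that was 0.0537 on TPM and 0.528 with the length trend removed, and Ighm was at 662 ± 78.5 and 752 ± 119 CPM. The 12 measured erythroid markers had a median of 1.31, and 0 passed edgeR's test without the block, where 8 had an unadjusted p under 0.05 and DESeq2 called 2. With the block all 12 rose. The erythroid median was 0.6 without PGE2 replicate 2, and 0.6 to 1.8 over the libraries left out. Camera called this list higher (adjusted p = 0.0156; adjusted p = 0.715 with an estimated correlation), and its adjusted p was 0.0614 without PGE2 replicate 2, 0.0585 without vehicle replicate 1 and 0.0531 without the hemoglobin genes (1.37e-05 to 0.715 over the alternatives). Hbb-bs was at 3838 ± 2623 CPM in vehicle and 9801 ± 6578 CPM in PGE2, with an edgeR adjusted p of 0.156 that was 0.000279 with the block. Within the same-numbered pairs the summed TMM-scaled CPM of hemoglobin genes was 3.62, 2.56 and 2 times higher with PGE2. Of 9 measured eosinophil markers, 6 fell, as when adjusted over the list alone, and 2 fell without PGE2 replicate 2 and 2 without PGE2 replicate 3 (camera adjusted p = 0.0934). Prg2 went from 118 ± 46.2 to 55.4 ± 14.3 CPM with an edgeR adjusted p of 0.0235, and 0.0783 and 0.0819 without PGE2 replicates 2 and 3 (0.00018 to 0.0819 over the alternatives). Of 13 T or NK cell markers, 0 passed edgeR's test, 1 had an unadjusted p under 0.05, DESeq2 called 0, and 5 passed with the block (camera adjusted p = 0.648). Of 8 megakaryocyte or platelet markers, 0 passed edgeR's test, 1 had an unadjusted p under 0.05, DESeq2 called 0, and 1 passed with the block (camera adjusted p = 0.398). Of 9 stem or progenitor cell markers, 0 passed edgeR's test, 0 had an unadjusted p under 0.05, DESeq2 called 0, and 1 passed with the block (camera adjusted p = 0.754). Of 16 monocyte or macrophage markers, 1 rose and 3 fell, as when adjusted over the list alone, and 2 rose and 4 fell with the block (camera adjusted p = 0.754). Without vehicle replicate 2 the monocyte marker that rose did not pass. Mpeg1 fell by 0.67 ± 0.13 on the log2 scale. Of 7 basophil or mast cell markers, only the histamine synthesis gene Hdc rose, from 691 ± 50.3 to 1953 ± 225 CPM (camera adjusted p = 0.687). Of 8 dendritic cell markers, 2 fell, and 1 rose and 2 fell with the block, while 1 fell without each library other than PGE2 replicate 3 (camera adjusted p = 0.3). Of 8 stromal or endothelial markers, 1 rose and 1 fell, and 2 rose and 1 fell with the block (camera adjusted p = 0.754). No stromal marker was called lower by edgeR without PGE2 replicate 2, PGE2 replicate 3 or vehicle replicate 1, and 2 rose without PGE2 replicate 3. In the dendritic and stromal lists the first counts were the same when adjusted over the list alone. Of 13 mature neutrophil markers, 2 rose and 6 fell, and 2 rose and 7 fell when adjusted over the list alone (camera adjusted p = 0.3). The fallen neutrophil markers numbered 3 without each of PGE2 replicate 2, PGE2 replicate 3 and vehicle replicate 2. Csf3r, the receptor gene for G-CSF, went from 5152 ± 420 to 2697 ± 222 CPM and Ly6g from 175 ± 27.5 to 96.0 ± 10.6 CPM.

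Of the 37 lists, camera called 6 higher and 5 lower with the preset correlation and 0 with an estimated one, where 3 had an unadjusted p under 0.05. The limma fry test, which asks whether a list moves one way on balance, called 13. It did not call the B cell or erythroid markers (fry adjusted p = 0.135 and 0.192). It did call the prostanoid, angiogenic, Toll-like receptor and unfolded protein lists, which camera did not (fry adjusted p = 0.00876, 0.00876, 0.0452 and 0.0358). The median and the mean differed in sign for angiogenic genes (-0.01 and 0.32), cholesterol genes (-0.03 and 0.09), antigen presentation genes (-0.05 and 0.13), basophil or mast cell markers (-0.16 and 0.07) and monocyte or macrophage markers (-0.13 and 0.11). Camera took the direction of the mean for the angiogenic, cholesterol, antigen presentation and basophil or mast cell lists, and that of the median for the monocyte or macrophage list.

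**Figure D3:**
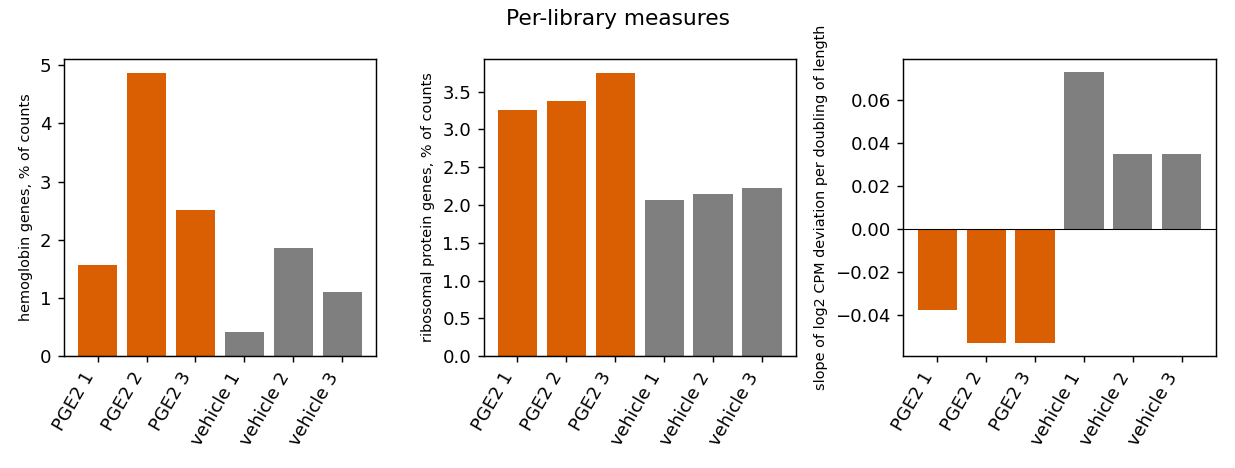
Per-library share of counts in hemoglobin genes and in ribosomal protein genes (percent), and the slope of log2 CPM, as the deviation from each gene's mean, per doubling of transcript length; orange bars are PGE2 and gray bars vehicle libraries. Slopes ran from -0.053 to -0.038 in PGE2 and from 0.035 to 0.073 in vehicle libraries.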

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

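The alternatives on library totals, hemoglobin genes, halved counts and the length and GC trend were chosen after the data were seen. Genes lower with PGE2 numbered 1627 to 2262 when 1 library was left out, and 602 with a minimum log2 fold change of 1. Genes higher numbered 1005 to 1541 when 1 library was left out, with 1005 without vehicle replicate 2 and 1063 without PGE2 replicate 2, where fewer samples were tested. They numbered 2648 with the replicate block, 966 on log2(TPM + 1), where 12621 genes were tested, and 404 with the minimum fold, which removes small changes by construction. The cause of the gap on TPM was not tested. The median log2 fold change of all genes was 0.038, against -0.064 on TPM and 0.131 on library totals, so small changes are relative to the scaling. Of the 1618 higher genes, 1612 kept their call with the block, and of the 2278 lower genes 2276. The lists called numbered 10 to 13 when 1 library was left out, 13 with the block and 0 with an estimated correlation. Correlation between members does not account for all of that loss. The adhesion list had an estimated correlation of 0.006, under the preset 0.01, yet its unadjusted camera p went from 0.00165 to 0.0322.

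Of 143 named genes that passed, 120 kept their call under every alternative run for them, 23 lost it under at least 1 and 0 changed sign. Of the 23 that did not pass, 8 changed sign. Ptger4 ranged from -0.013 to 0.12, Irf8 from -0.034 to 0.18, Myb from -0.012 to 0.13, Sox4 from -0.046 to 0.49, Itgax from -0.17 to 0.03, Prss34 from -0.70 to 0.20 and Pf4 from -0.37 to 0.68 when 1 library was left out. On TPM, Ptger4 was at -0.069, Irf8 at -0.041 and Myb at -0.028, and on library totals Itgax was at 0.035. With the length and GC trend removed, Pf4 was at -0.23, at -0.15 with GENCODE lengths and at -0.23 with the block as well, where Ighm was at -0.002. For these, the cause was not tested. A change of pseudocount was not run, since the values were counts. With the counts halved, as they count reads and not fragments, 1736 genes were higher and 2327 lower. Depth limits what can be said of the genes under the filter, as 15947 of 45777 were tested.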

Other observations

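The tests on length, cell types, hemoglobin and gene families were chosen after the results were seen, and the splits of the libraries before. Bootstrap intervals of medians below resample the genes of a list and leave out the spread between libraries. Ribosomal protein genes were a group outside the fixed lists: of 77 measured, 74 rose and 0 fell with edgeR (75 rose and 0 fell with DESeq2), with a median log2 fold change of 0.59. As a share of counts they took 3.26 to 3.75% in the PGE2 and 2.06 to 2.23% in the vehicle libraries. Of 78 mitochondrial ribosomal protein genes 27 rose and 1 fell, of 34 proteasome subunit genes 11 rose, and of 43 translation initiation factor genes 11 rose and 2, Eif4e3 and Eif4g3, fell (0 without PGE2 replicate 2, PGE2 replicate 3 or vehicle replicate 1 and 1 without any other library). With a length and GC trend fitted on all genes removed, 41 ribosomal, 11 mitochondrial ribosomal, 2 proteasome and 8 initiation factor genes rose, and on TPM 56, 12, 3 and 6. The replicate block gave 19 proteasome genes that rose and 2 that fell. Mitochondrial ribosomal genes that rose numbered 15, 15, 15, 11 and 17 without PGE2 replicates 2 and 3 and vehicle replicates 1, 2 and 3, and proteasome genes that rose numbered 6, 6 and 7 without PGE2 replicate 2, vehicle replicate 2 and vehicle replicate 3. With a preset correlation and adjusted over 5 families, camera gave 3.98e-24 for ribosomal proteins (adjusted p = 0.0814 with an estimated correlation), 2.23e-09 for mitochondrial ribosomal proteins (adjusted p = 0.0405 with an estimated correlation), 2.43e-05 for the proteasome (adjusted p = 0.0814 with an estimated correlation) and 0.00226 for initiation factors (adjusted p = 0.0814 with an estimated correlation). Of 16 clock genes 3 rose and 2 fell, and 1 fell without each of PGE2 replicates 2 and 3 and vehicle replicates 2 and 3 (camera adjusted p = 0.512), with Per1 at 1.08 ± 0.12 and Bhlhe40 at 1.96 ± 0.11 against Per2 at -1.88 ± 0.33 and Cry1 at -0.42 ± 0.11 on the log2 scale.

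The rise of oxidative phosphorylation and ribosomal protein genes may in part be a length effect, since both groups have short transcripts (median 1322 and 821 bases). These lengths were derived from the deposited counts and coverage, and had a Spearman correlation of 0.734 with the longest GENCODE transcripts. Across genes, log2 fold changes went with transcript length (Spearman -0.308, where genes are not independent replicates). The slope was below 0 in all 3 PGE2 and above 0 in all 3 vehicle libraries, so length and treatment are confounded. Slopes were taken against each gene's mean over the libraries. Opposite signs of the group averages thus follow from that correlation and are not separate evidence. With a length and GC trend fitted on other genes removed, the ribosomal protein median went from 0.59 (95% bootstrap interval 0.55 to 0.67) to 0.32 (0.28 to 0.36), and 43 of 77 genes still rose. The fitted trend thus did not take away the whole rise. By the rule written for this test, the outcome for ribosomal protein genes was undecided. The oxidative phosphorylation median went from 0.27 (0.17 to 0.47) to 0.08 (0.01 to 0.18), close to the 0.044 left in the genes with the shortest transcripts, and camera's call was lost with lengths from the files and not with GENCODE lengths. For oxidative phosphorylation genes, and for the part of the ribosomal rise that was removed, a length effect cannot be told apart from a response of short genes to PGE2, since the trend itself follows the groups.

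The fall of specific and gelatinase granule genes was set against a loss of neutrophil RNA, fewer dividing precursors and length. Mature neutrophil markers outside that list had a median of 0.00 (-0.56 to 0.38), above the granule interval of -1.18 to -0.64 (3 of the 13 neutrophil markers are also granule genes and were left out). By the rule written for this test, that argues against a lower neutrophil share as the whole cause. The markers did not move alike, however. Csf3r at -0.93, Ly6g at -0.87 and Cxcr2 at -0.35 passed as lower, and Trem1 at 0.75 and Il1r2, higher still, passed as higher. Stfa2l1 at -0.56, Retnlg at 0.01, S100a8 at 0.17 and S100a9 at 0.22 did not pass, nor did Mxd1. Csf3r and Ly6g lay inside the granule interval, so the median is weak ground on the neutrophil share. The cell cycle median was 0.16 (0.10 to 0.34), where fewer dividing precursors of all kinds would lower it. The list is not particular to neutrophil precursors, and the medians of B cell and erythroid markers were higher with PGE2. It thus cannot decide on a loss of neutrophil precursors. Azurophil granule genes had a median of -0.31 (-0.79 to -0.01), where 1 of 11 rose and 2 fell. With the length trend removed the granule median was -1.10 (-1.28 to -0.73), which argues against length bias. A response to PGE2, or a shift between stages of maturation, may stand behind the fall. Such a shift was not tested.

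The rise of B cell and erythroid markers may come from RNA of other cells. A lower neutrophil share would raise the markers of other types alike. Yet 7 of 8 other lists had intervals wholly below the erythroid one of 1.07 to 1.36 (median 1.31). Without PGE2 replicate 2, where the erythroid median was 0.60 (0.50 to 0.68), 4 still did. These values argue against a lower share as the whole cause of that rise. The intervals resample genes, and erythroid markers move together between libraries (estimated correlation 0.83). They thus understate the error of the treatment effect, and the erythroid median ran from 0.6 to 1.8 over the libraries left out. For B cell markers, at 0.63 (0.21 to 0.79), a lower share cannot be told apart from other causes. The intervals of 2 lists lay wholly below (dendritic cells, and basophils or mast cells), but only 1 without PGE2 replicate 3 or without vehicle replicate 1. The eosinophil interval of -1.99 to 0.35 (median -1.07) overlapped, and the medians of T or NK cells at 0.28 and megakaryocytes or platelets at 0.54 lay inside. Without PGE2 replicate 2 those 2 medians were -0.01 and 0.20, below the B cell interval of 0.31 to 0.91. Without vehicle replicate 1 the T or NK cell median was 0.03, below the B cell interval of 0.24 to 0.79. With any other library left out, both medians lay inside or above. The summed TMM-scaled CPM of hemoglobin genes was at least 2 times higher with PGE2 in each of the 3 same-numbered pairs. If the numbers pair the libraries, that argues against a single library as the only source of the erythroid rise. The labels do not state the pairing, and without it the groups overlapped. Hemoglobin genes took 1.57% of counts in PGE2 replicate 1 and 1.86% in vehicle replicate 2. A change in B cells or red cell precursors themselves, such as different survival in culture, stays open and was not tested.

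The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1618 higher and 2278 lower genes, and 1 of the 10 splits, the real one, gave as many in each direction. The highest count in either direction in another split was 0 (edgeR; DESeq2 was not run on these), including the 3 others that part all 3 same-numbered pairs, with 93 to 738 genes at an unadjusted p under 0.05 against 5902. For the lists, 3 of the 10 splits called at least 11, and the highest of the others called 14. The splits that part 1 pair called up to 14 lists and the others that part 3 pairs up to 9. Every other split mixes PGE2 and vehicle libraries unevenly. Part of the treatment effect thus stays between its sides and also adds to the spread within them. The 0 genes called there were largely set by this design, and the lists called there may hold part of the response. With an estimated correlation camera called 0 lists, 3 had an unadjusted p under 0.05 and fry called 13. A camera call with the preset correlation is therefore weak evidence by itself here.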
